A study of Mus musculus with 8 samples.

How the data were processed

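Total RNA from control and ethanol-exposed mouse cortical neurosphere cultures was hybridised together on 8 two-colour arrays of the 22K mouse format. Per the labels' protocols, the cultures grew in serum-free medium with 20 ng/ml basic fibroblast growth factor, 20 ng/ml epidermal growth factor and 0.15 ng/ml leukaemia inhibitory factor. RNA was extracted with Trizol and purified on RNeasy columns, and 1 µg was labelled with a Genisphere 3DNA kit for Cy3 and Cy5, in which dye-bearing dendrimers bind capture sequences on the cDNA's primers. The scanner, the background correction and the normalization are not given in the sources used here. The labels number the arrays as replicates 1 to 8 and carry array codes: a3, a5, a1r and a2r with ethanol-exposed RNA in Cy3, and b3, b4, b5 and b1r with ethanol-exposed RNA in Cy5. Nothing says which arrays came from separate cultures, so that p-values measure the spread between these arrays, which may be technical.

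The file used holds the log2 ratios that the authors deposited, 1 per probe and array, with no intensities. What those values are was worked out from the table. On every array each value below a ratio of 0.1 equalled the log2 of a ratio rounded to 3 decimals plus 1 constant per array (100% of such values within a tolerance of 0.0011 on the log2 scale, against 6.5% to 8.7% at other constants). The smallest ratio this rounding can hold is 0.001, so that a value there is a bound. Each array's single highest value, held by 108 to 464 probes, equals that constant plus the log2 of 100000. Between 2565 and 5200 values per array are exactly 0, while only 66 to 117 others lie within 0.01 of 0. Both kinds were taken as ratios that could not be computed and were treated as missing. The medians of the computable values were -0.375, -0.435, -0.324, -0.331, 0.313, 0.229, 0.023 and 0.516 for replicates 1 to 8. As 7 of the 8 lay further than 0.1 from 0, every array was centred on its median, with the values as deposited as an alternative. Dim probes could not be told from bright ones except by the number of arrays on which a ratio was not computable. The number of arrays limits the precision.

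The direction of the ratios stayed unknown. The sample records list control RNA as the first channel on all arrays, while the series' own design text puts ethanol-exposed RNA first on the 4 dye flips, and no label says which channel was divided by which. The rule set before the data were examined used the 3 pairs of arrays that share a code number across the orientations. The correlations of their deviations from their orientation's mean were 0.014, -0.016 and 0.044, within 0.1 of 0. The arrays of a pair thus did not deviate together. That does not exclude cultures shared by arrays of the same code number, since noise between arrays could hide them. Neither reading was settled. Both parts of the ratio are therefore reported, without a direction.

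Probes with computable values on at least 3 arrays of each orientation were tested, 15345 of 21582, of which 10486 had values on all 8 arrays. Each was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 2 coefficients, the part shared by the orientations and the part that turns with the dye. P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. SEs are those of the moderated fit. Probes were named through the platform's annotation, which is old, with symbols updated by Entrez number through a table of the GRCm38.p6 assembly. Of all probes 16635 had 1 gene symbol, 113 had several and were left unnamed, and 4834 had none. Entrez numbers matched for 15957. The tested probes covered 11400 named genes. Neither the files nor the labels name a genome build, so no coordinates are given.

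The 25 gene lists were fixed before the data were examined. They cover cell types the cultures could hold (neural progenitor, neuronal, astrocyte, oligodendrocyte lineage) and others (microglia and macrophages, endothelial and mural cells, meningeal fibroblasts, erythroid cells), cell cycle, apoptosis, extracellular matrix, integrins and adhesion, axon guidance, neurotransmitter receptors, angiogenic cytokines, ethanol, aldehyde and retinoid metabolism, oxidative stress, heat shock and endoplasmic reticulum stress, cholesterol synthesis, glycolysis and hypoxia, Notch, Wnt, Shh and Fgf signalling, chromatin and DNA methylation, imprinted genes, ribosomal proteins and the respiratory chain. A gene with several probes was represented by the probe with the most values, then the first identifier. Camera needs complete data, so the lists were tested on the moderated statistics of the fit with its variant for ranked values, cameraPR, with a preset correlation of 0.01. Camera with an estimated correlation and fry were run on the 8233 genes with values on all 8 arrays, where 24 of the lists kept at least 5 members. An exact two-sided sign-flip test over the 8 array medians was added for each list.

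Named genes followed a rule set beforehand. For each part, these were the 20 genes with the largest absolute value among probes past the threshold whose ratio, turned where needed, had 1 sign on all arrays with a value. Where fewer passed, the places were filled in order of unadjusted p. In addition each list gave its members past an adjusted p of 0.05, over all probes or over the list alone, at most 4 per list by unadjusted p, or else the 2 with the smallest p. Cell cycle members beyond these 4, members of other lists named as not passing, and the second probes of Plk1 and Pax6 were chosen after their values were seen.

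The fit was tested on simulated arrays with the probes' own spread and missing values. In the shared part it recovered 3, 27, 45 and 50 of 50 probes changed by 1, 2, 3 and 4 on the log2 scale, with 5 false calls among 130. In the turning part it recovered 3, 28, 49 and 50 of 50, with 4 false calls among 134. A list of 31 genes shifted by 0.5 was called in either part and no other list was. The noise was drawn independently for each probe, so lists whose members move together were not tested. Cell cycle genes did so in the real arrays, with an estimated correlation of 0.338. The recovery rates hold for arrays with 50 changed probes of each size and do not give the power of the real arrays. Alternatives covered the centring, the scale between arrays, the probe filter, the dye term, the reading of the ratios, the code number as a block or as the unit of replication, array weights, the arrays with an r code, each array left out, the variance model, a minimum fold of 1.2 and the test of the lists. Alternatives chosen after the data were seen were keeping the exact zeros and highest values, centring within brightness classes, and leaving out b4 and b1r.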

Results

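Gene expression was measured in neurospheres, free-floating clusters of neural stem and progenitor cells, grown from the cortex of mouse embryos at gestational day 12.5. The cultures were either left untreated or exposed to ethanol at 320 mg/dl for 5 days while they proliferated. Both were then differentiated by withdrawing epidermal growth factor and leukaemia inhibitory factor, and the exposed cultures spent these 3 days without ethanol. Control and ethanol-exposed RNA were hybridised together on 8 arrays of 21582 probes. Ethanol-exposed RNA carried Cy3 on 4 arrays (replicates 1 to 4) and Cy5 on the other 4 (replicates 5 to 8). Between 16274 and 18802 probes per array had a computable log2 ratio, which is 75.4% to 87.1% of the probes. A total of 15345 probes had values on at least 3 arrays of each orientation and were tested.

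The comparison of control with exposed cultures asks whether ethanol met during proliferation leaves expression differences that persist through differentiation. The sources used here do not say which condition, or which dye, stands above the line in the deposited ratios. Each probe's log2 ratio was therefore split into 2 parts. The shared part is the mean over both orientations and holds the ethanol effect if the ratios were deposited as 1 condition over the other. The turning part is the deviation that changes sign with the dye orientation, and holds the ethanol effect if the ratios were deposited as 1 dye over the other. Under either reading the remaining part is the dye effect. Signs are given as deposited: a positive shared part means a ratio above the array's median on average over the orientations, though not always in each, and a positive turning part means a higher ratio where ethanol-exposed RNA carried Cy5. Neither sign says whether ethanol-exposed cells had more or less of a transcript.

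In the shared part, most genes of cell division lay on the positive side. The cell cycle list had 31 measured members with a median of 0.93 on the log2 scale (0.60 without replicate 3 and 0.75 to 1.18 without any other array), and 21 of them were positive. After adjustment over the list alone 11 members passed, 10 of them positive (± SE of the fit, n = 8 arrays, fewer for Cdk1). Aurka and Birc5, of mitotic chromosome segregation, read 2.52 ± 0.66 and 1.48 ± 0.41. The replicative helicase subunits Mcm3 and Mcm5 read 1.76 ± 0.43 and 1.60 ± 0.43, and the cyclins Ccnd1 and Ccne1 1.98 ± 0.60 and 1.19 ± 0.38. The kinases Cdk1 and Cdk2 read 1.93 ± 0.63 and 1.34 ± 0.31. The ribonucleotide reductase subunit Rrm1 read 1.68 ± 0.52 and the spindle checkpoint kinase Bub1b 1.39 ± 0.43. The probe that stood for Plk1 was negative, at -1.31 ± 0.39, whereas a second Plk1 probe read 1.51 ± 0.46. Cdk2, Mcm3, Mcm5 and Aurka were positive on 8 of 8 arrays. Aurka's size leaned on replicate 6, where it read 6.70 against 0.35 to 3.61 on the other arrays. Mki67 and Top2a, also proliferation genes, read -0.39 ± 0.51 and -0.59 ± 0.65 and did not pass. The 10 negative members also included relatives of the genes that passed: Mcm4 at -0.20, Mcm7 at -0.18, Aurkb at -0.42 and Bub1 at -0.82, none passing.

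**Figure D1:**
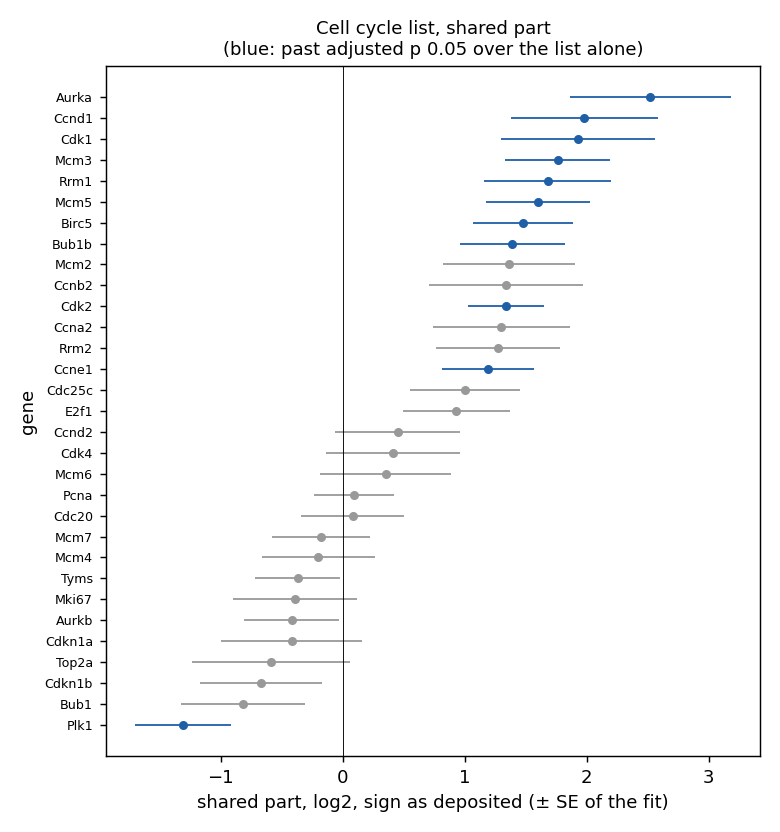
Shared part (log2, sign as deposited) of the 31 measured genes of the cell cycle list, with the SE of the fit over the arrays with a value, which is all 8 for 28 of the genes. Blue marks genes past an adjusted p of 0.05 over the list alone. Of the 11 blue genes 10 lie above 0, from 1.19 for Ccne1 to 2.52 for Aurka, and Plk1 lies at -1.31.

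The cell cycle list was called against all other genes by limma's camera with a preset correlation of 0.01 (adjusted p = 9.58e-05 over 25 lists), and its adjusted p was 0.745 with an estimated correlation, which was 0.338 between members. Its median was positive on 7 of 8 arrays, ranging from -0.30 on replicate 4 to 2.54 on replicate 3 (exact sign-flip test over the 8 array medians, two-sided p = 0.0156, adjusted p = 0.195 over the lists, where 0.0078 is the smallest p possible). Over all 15345 probes no member of any list passed in the shared part.

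Ribosomal protein genes and subunits of the mitochondrial respiratory chain were also positive in the shared part, by small amounts. The ribosomal protein list had a median of 0.33 with 54 of 64 members positive (adjusted p = 9.58e-05; adjusted p = 0.745 with an estimated correlation). Its array medians lay between 0.51 and 1.23 on the arrays with ethanol in Cy3 and between -0.25 and -0.05 on those with ethanol in Cy5, so that this list was not shared by the orientations. The respiratory chain list had a median of 0.33 with 53 of 67 members positive (adjusted p = 0.000335, or 0.618 with an estimated correlation). Its array medians lay between 0.23 and 0.67 with ethanol in Cy3 and between -0.11 and 0.24 with ethanol in Cy5. The list was led by the ATP synthase subunits Atp5g2 at 1.64 ± 0.43 and Atp5o at 1.02 ± 0.34, neither of which passed. Enzymes of cholesterol synthesis had a median of 0.50 with 14 of 18 positive (adjusted p = 0.0221; adjusted p = 0.745 with an estimated correlation). Over that list alone 3 enzymes passed, Fdps at 1.35 ± 0.40 and Mvk at 1.15 ± 0.35 on the positive side and the isomerase Idi1 at -1.59 ± 0.48. Oxidative stress genes had a median of 0.24 with 18 of 23 positive and a positive median on 8 of 8 arrays (adjusted p = 0.0457; adjusted p = 0.618 with an estimated correlation), with the haem oxygenase gene Hmox1 at 1.10 ± 0.34, not past the threshold. The calls for cholesterol synthesis and oxidative stress ended when single arrays were left out, with adjusted p up to 0.131 and 0.117. Of 26 alternatives of the same reading, 9 ended the call for cholesterol synthesis and 13 that for oxidative stress. The 13 included the values as deposited, probes with a value on all 8 arrays, and leaving out the r arrays. With fry, which asks whether a list moves on balance 1 way, 3 lists passed, and cell cycle did not (adjusted p = 0.309). The 3 were ribosomal proteins (adjusted p = 0.0255), the respiratory chain (adjusted p = 0.0255) and oxidative stress (adjusted p = 0.0154). Fry's mixed test asks whether members move in either direction, without comparing them with other genes, and gives no direction. It passed 17 of 24 lists in the shared part, cell cycle among them (adjusted p = 0.00783).

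**Figure D2:**
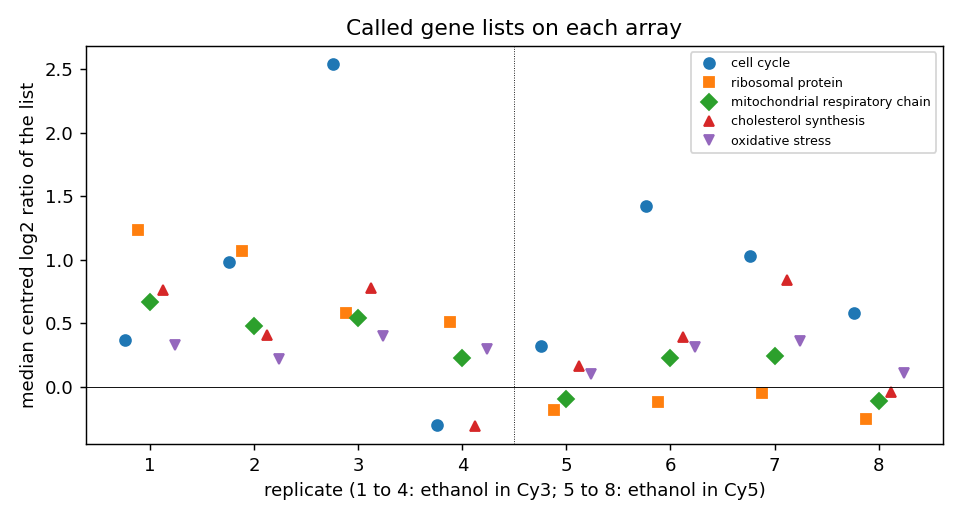
Median centred log2 ratio (sign as deposited) of the 5 gene lists called in the shared part, on each of the 8 arrays; the dotted line parts the arrays with ethanol in Cy3 (replicates 1 to 4) from those with ethanol in Cy5 (replicates 5 to 8). Cell cycle medians lie above 0 on 7 arrays, whereas ribosomal protein medians lie above 0 only on the 4 arrays with ethanol in Cy3.

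Neural cell-type markers did not pass as lists by camera in the shared part. Neuronal genes had a median of -0.29 (adjusted p = 0.644), and the microtubule-associated protein gene Dcx of migrating neurons, at -1.88 ± 0.46, passed over that list alone. Neurotransmitter receptors had a median of -0.31 (adjusted p = 0.417) and neural progenitor genes 0.26 (adjusted p = 0.727); over their own lists the GABA receptor subunit gene Gabrg1 passed at -1.86 ± 0.43 and the bHLH inhibitor gene Id2 at -1.26 ± 0.31. Astrocyte genes had a median of -0.46 (adjusted p = 0.418) with Clu at -1.83 ± 0.57, and oligodendrocyte lineage genes -0.08 (adjusted p = 0.960) with Cldn11 at -1.92 ± 0.55, neither gene passing. Integrin and adhesion genes had the lowest list median, -0.64, with 15 of 18 members negative, and did not pass (adjusted p = 0.088). Imprinted genes had a median of 0.21 (adjusted p = 0.644). The other 13 lists each had an adjusted p of 0.960. Their medians were -0.08 for apoptosis, in which the death receptor gene Fas passed over the list alone at -1.84 ± 0.41, -0.25 for axon guidance, -0.10 for ethanol, aldehyde and retinoid metabolism, -0.13 for glycolysis and hypoxia, -0.09 for angiogenic cytokines, -0.05 for chromatin and DNA methylation, -0.01 for Notch, Wnt, Shh and Fgf signalling, 0.02 for extracellular matrix and 0.18 for heat shock and endoplasmic reticulum stress. For cells the culture should hold few of, they were -0.17 for endothelial and mural cells, -0.15 for meningeal fibroblasts, 0.04 for microglia and macrophages, and 0.02 for erythroid cells. Median, mean and test differed in sign for 7 of the 25 lists, none of them called by camera.

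No single probe passed an adjusted p of 0.05 in the shared part with limma (smallest adjusted p = 0.136), while 2132 probes (13.9%) had an unadjusted p under 0.05 where chance gives 767. Of the 20 genes with the smallest unadjusted p, 17 were negative and 3 positive, and 19 had the same sign on every array with a value. Among the negative ones were the cytoskeletal linker Macf1 at -3.00 ± 0.45, the splicing regulator Mbnl2 at -2.57 ± 0.43, the transcription factor Elf1 at -2.37 ± 0.37, the mitochondrial dehydrogenase Aldh6a1 at -2.42 ± 0.38 and the G-protein signalling regulator Rgs14 at -2.12 ± 0.33. The positive ones included the DNA replication clamp loader subunit Rfc2 at 1.75 ± 0.28 and the mitotic ubiquitin-conjugating enzyme Ube2c at 2.14 ± 0.37. Both lie outside the fixed cell cycle list and were grouped by function only after they were seen. The third, the neuropeptide receptor gene Vipr2, at 3.15 ± 0.53, was positive on 4 of 7 arrays and had a turning part of -4.34. None of these passed (adjusted p 0.136 to 0.140). In simulated arrays with the same spread, 3 of 50 probes with a shared part of 1, 27 of 50 with 2 and 45 of 50 with 3 were recovered. Even there, differences of less than 4-fold were often not detectable with 8 arrays. The simulation held 50 changed probes of each size, and many true changes ease the adjustment over all probes. Macf1, at -3.00 in the real arrays, did not pass, so these rates do not give the power there.

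In the turning part a small set of probes differed between the orientations. A pass did not require the sign to reverse on every array, which was checked only for the 20 named genes. Of 15345 probes 239 passed (limma, smallest adjusted p = 1.42e-06), 118 positive and 121 negative, and 2122 (13.8%) had an unadjusted p under 0.05. The count and the balance of signs depended on the processing: 417 probes passed, 312 of them positive, with the values as deposited, 144 passed without replicate 8 and 84 without the r arrays (replicates 3, 4 and 8). The turning part was at least 16-fold for 91 of the 239, 46 positive and 45 negative, and reached 8.02 on the log2 scale, whereas no probe had a shared part of 16-fold. The 20 named genes had turning parts of 86.7-fold to 238-fold, 11 positive and 9 negative, and 9 of them carry only clone names. Among the others were Gpbp1l1 at 7.17 ± 0.27, the nuclear receptor coactivator Ncoa3 at 7.50 ± 0.37, the helicase Brip1 at 7.68 ± 0.41, the acyl-CoA thioesterase Acot12 at 7.25 ± 0.42 and the inflammasome gene Naip5 at 7.01 ± 0.32 on the positive side. On the negative side were the lipid kinase Pi4k2b at -7.40 ± 0.36, the membrane protease St14 at -7.14 ± 0.36, the antigen peptide transporter Tap2 at -6.78 ± 0.38 and the metalloreductase Steap4 at -6.83 ± 0.48. The deposited rounding cannot hold a ratio under 0.001, and 6 of the 20 named genes, Brip1, Acot12 and Gprc5c among them, had 1 value at that floor, as did 10 of the 239 probes on at least 1 array, so that their sizes are imprecise and the order of these genes by size is not resolved. Other probes of the same genes gave smaller values: Gpbp1l1 read -0.35 on its other probe, Pi4k2b read -0.50 and Cntn1, called at 4.77, read 1.65. Over the 12 genes with another probe outside the 91, the median of the other probes, turned to the side of the called probe, was 0.35.

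**Figure D3:**
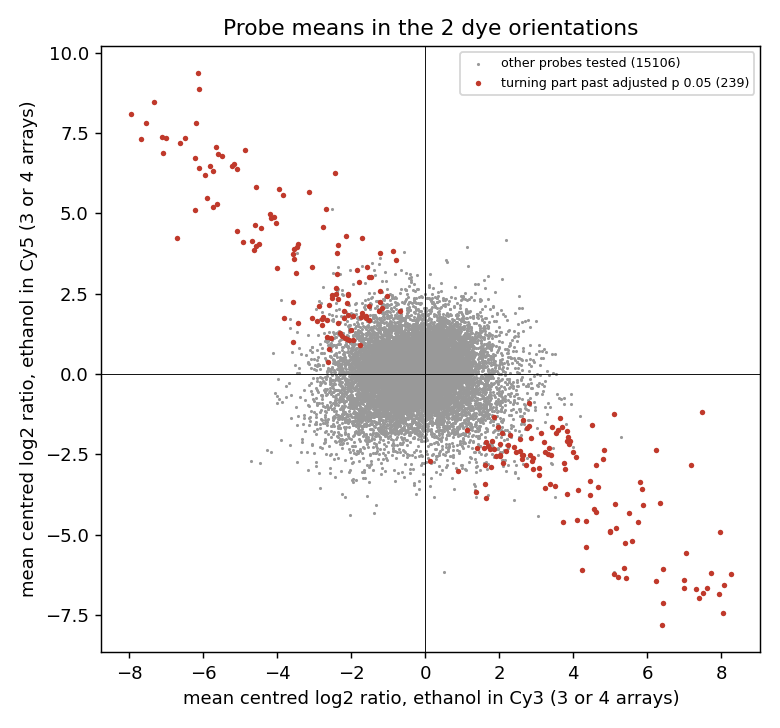
Mean centred log2 ratio (sign as deposited) of each of 15345 probes on the arrays with ethanol in Cy3 (horizontal) and in Cy5 (vertical); red marks the 239 probes whose turning part passed. The red probes run from upper left to lower right, with 91 of them turning by at least 16-fold.

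Adjusted over all probes, 239 of 15345 probes passed in the turning part. With 1 probe standing for each gene, 9 of the 537 measured genes of the fixed lists did so, a similar share, from 9 lists. They were the alcohol dehydrogenase Adh4 at -4.39 ± 0.47, the matrix metalloproteinase Mmp9 at -5.71 ± 0.47, the anaphase activator Cdc20 at -3.01 ± 0.42, the growth factor gene Igf2 at -2.82 ± 0.36, the adhesion molecule Cntn1 at 4.77 ± 0.72, the ligand Wnt3a at 3.71 ± 0.48, the Polycomb subunit Eed at 2.28 ± 0.40, the glutathione synthesis gene Gclm at 1.88 ± 0.33 and the BH3-only gene Pmaip1 at 1.90 ± 0.37. Cntn1's size leaned on replicate 6, where it read 9.07 against 2.23 to 3.42 on the other arrays with ethanol in Cy5. Of 55 other probes of list genes 1 passed, a probe of the Hedgehog receptor Ptch1 at -6.26 ± 0.41, against -0.65 for the probe that stood for the gene. That probe was looked for after the results were seen. Over their own lists a further 9 passed: Adh1, Crabp1, Bcan, Cycs, Cdh5, Tyms, Fzd8, C1qa and Pax6. Crabp1, Bcan and Cdh5 had values on only 6 arrays. Pax6 read 3.82 ± 0.84, against 0.56 ± 0.56 on its other probe, which did not pass. With ethanol in Cy3 its first probe read 3.04 on replicate 3, against -4.96 to -3.40 on the other arrays. Of the 25 lists only ribosomal proteins were called by camera, on the negative side, with a median of -0.39 and 52 of 64 members negative. Their adjusted p was 0.00152 at the preset correlation and 0.946 with an estimated correlation. That call ended without centring of the arrays. The median turning part of all probes was 0.11 after centring and 0.42 as deposited. The other 24 lists had camera adjusted p from 0.532 to 0.964 and medians from -0.56 for angiogenic cytokines to 0.39 for microglia and macrophages. Fry's mixed test, which gives no direction, passed 10 of 24 lists in the turning part, Notch, Wnt, Shh and Fgf signalling among them (adjusted p = 3.6e-05). The median was 0.06 for cell cycle, 0.30 for neuronal, -0.06 for astrocyte and -0.06 for neural progenitor genes. Median, mean and test differed in sign for 9 lists, none of them called by camera.

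Arrays resembled each other within an orientation more than between orientations. Across the tested probes, which are not independent replicates, the mean Pearson correlation between arrays was 0.293 (0.250 to 0.372 over 6 pairs) with ethanol in Cy3 and 0.211 (0.143 to 0.330 over 6 pairs) with ethanol in Cy5. Between the orientations it was -0.084 (-0.279 to 0.074 over 16 pairs).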

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

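The tests on other probes of the same genes, on random lists and on chance differences in growth were chosen after the results were seen; the tests on the splits, on b3 and b5, on brightness centring and on leaving out a1r were written before theirs.

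The largest difference between the dye orientations lay in 239 probes whose turning part passed, 91 of them by at least 16-fold, including Gpbp1l1, Ncoa3, Pi4k2b and St14. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many probes, and the highest of the others gave 1. That argues against chance, but no share below 1 of 35 is possible, so chance is not excluded. The splits also cannot tell the dye from another difference between the 2 sets of arrays. If these genes responded to ethanol, their other probes should turn too. Over the 12 genes with another probe outside the 91, the median of the other probes on the side of the called probe was 0.35 (95% bootstrap interval -0.09 to 0.58). The called probes had a median of 5.18, and only Cntn1's other probe, at 1.65, exceeded 1. Other probes that were themselves among the 91 were left out beforehand, and 1 of the 12 values averages 87 probes of Tcrb-V8.2. The comparison could thus not find genes whose probes turned together, and does not decide against a response. Signal of a probe in 1 dye regardless of the RNA, such as probe-specific capture of the labelling reagent, needs other probes near 0. It would turn with the dye only if the ratios were deposited as 1 condition over the other. Under that reading it stays a candidate explanation. The interval of the other probes includes 0, and its upper bound of 0.58 lies under the limit of 1 set after the values were seen. The probes left out limit this comparison too. Transcript variants read by 1 probe of a gene stay open, as do the 79 probes without such a comparison.

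Cell cycle genes in the shared part, with a median of 0.93, were the gene group with the largest shift. The shift did not come from array a1r alone, where the list's median was 2.54: without it the median was 0.60 and the adjusted p 0.00305 at the preset correlation, but over all arrays the adjusted p was 0.745 with an estimated correlation and 0.309 with fry. Biases of single probes, or a trend with brightness, unrelated to function stay open: 0 of 10000 random lists of the same size and number of computable arrays reached that median (highest 0.43), but this restates the call, 28 of the 31 members lie in the class computable on all arrays, within which brightness was not matched, and the probes of Plk1 read -1.31 and 1.51. Growth of the paired cultures differing by chance stays open and cannot be told apart from an effect of ethanol, because the exact sign-flip p of 0.0156 over 8 arrays cannot pass an adjustment over 25 lists and the list's members move together (estimated correlation 0.338). An ethanol effect on proliferation is a hypothesis that no test here singles out, and its direction cannot be read here.

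Arrays b4 and b1r (replicates 6 and 8) stood apart, with mean correlations of -0.140 and -0.235 with the 4 arrays of the other orientation, against 0.001 for b3 and 0.036 for b5. Probes not computable on 3 arrays, which are not among the tested probes behind these correlations, had medians of -0.86 and -0.72 on b4 and b1r and of 0.26 to 0.86 on the other 6. Probes computable on all arrays went the other way, with medians of 0.29 and 0.17 on b4 and b1r and of -0.21 to -0.01 on the other 6. A flipped dye label on b3 and b5 is argued against by 164 probes of opposite sign on the first 4 arrays and on b4 with b1r. Their mean lay at least 4-fold from the array medians on each side. Of these, 4.9% kept the sign of the first 4 on both b3 and b5 and 80.5% turned on both. Brightness-dependent bias stays open: 92.4% of the gap in correlation was left after centring within brightness classes, but that limit, set before, was wrong as a test, since 68.3% of the tested probes lie in 1 class and a trend within it is left in place. No biological explanation was tested, as the labels put no difference between these arrays.

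Ribosomal protein genes differed between the orientations (limma camera adjusted p = 0.00152). The adjusted p was 0.946 with an estimated correlation and 0.066 with fry. In addition, 4 of the 35 splits gave as small an unadjusted p for the list (the smallest of the other splits 7.9e-06), so chance is not excluded.

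In 14 of 290 tested groups of 4 arrays (4.8%, where chance gives about 5%) 1 array lay far from the other 3. The median of the axon guidance list was 0.92 on replicate 1 against -0.03 to -0.02 on the others with ethanol in Cy3. In the same orientation, Zfp27 read -4.29 on replicate 3 against -2.59 to -2.41, Kdr -0.87 against 0.63 to 0.91 and H19 1.73 against 0.39 to 0.52, both also on replicate 3. Zswim5 read -1.33 on replicate 1 against -2.77 to -2.68, and Cldn11 -6.14 on replicate 1 against -2.06 to -1.29. Atp5o read -0.41 on replicate 4 against 0.93 to 1.11, and Sox10 -2.93 on replicate 2 against -1.65 to -1.54. With ethanol in Cy5, Hba-a1 read -3.81 on replicate 5 against -0.30 to -0.03, Tyms 1.59 on replicate 5 against 0.83 to 0.94, and Bcl11b -0.50 on replicate 5 against 0.71 to 0.81. Mest read 4.34 on replicate 6 against -0.49 to 0.31, Ctss 2.65 on replicate 6 against -0.21 to -0.02, and Mbnl2 -0.61 on replicate 8 against -2.99 to -2.69.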

How the results depend on the processing

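The shared part had 0 probes past the threshold under all alternatives of the same reading. Taken by the other reading, the ethanol effect is the turning part, with 239 probes, 1 list called and an adjusted p of 0.964 for cell cycle, and the dye effect is the shared part, with 0 probes and 5 lists. The turning part's 239 probes became 417 with the values as deposited (312 positive, against 118 of 239; 223 of the 239 remained), 84 without the r arrays (79 remained), and, in alternatives chosen after the data were seen, 143 with zeros and highest values kept (138 remained) and 108 without b4 and b1r (105 remained). In these 4 settings 93, 76, 81 and 74 probes passed with at least 16-fold. Leaving out each array gave 144 to 192 probes, of which 144 without replicate 8 and 155 without replicate 4 or 6; fewer arrays lower the power, and the cause was otherwise not tested. With the code number as a replicate block, 0 and 243 probes passed, and the block changed no list call; with arrays of a code number averaged into 5 replicates 161 probes passed, 149 of them among the 239; the 3 pairs sharing a number did not deviate together (0.014, -0.016 and 0.044). The lists called in the shared part, 5 in all, were 3 with probes on 1 array of each orientation, 3 with arrays of a code number averaged, 3 with zeros and highest values kept, 3 with fry, 0 with an estimated correlation and 3 to 6 with each array left out (3 without replicate 1, 2, 3 or 7). Cell cycle was called under 24 of 26 alternatives of the same reading, all of which kept camera's preset correlation of 0.01. The 2 without that preset lost the call, with an adjusted p of 0.745 with an estimated correlation and 0.309 with fry. The count of 24 therefore does not test the preset. With each array left out and the preset kept, the adjusted p was 7.58e-08 to 0.00333. The turning part's 1 called list, ribosomal proteins, lost its call, leaving 0 lists, with the values as deposited, with zeros kept (with or without the highest values), without b4 and b1r, with an estimated correlation and with fry, and was the 1 list called whichever array was left out. The cause of these changes was not tested. Under the alternatives of the same reading no named gene or list that was called changed sign, and of the 239 probes 1 did, with zeros and highest values kept. Of the 64 named genes of the turning part 29 were called, and only these could lose the call. Under the same reading 33 of 1525 comparisons over all 64 lost the call and 16 gained it. The named genes include the largest turning parts, so these counts do not describe the 239 probes. Under the other reading, where the turning part has 0 probes, a further 29 comparisons lost the call by construction. In the shared part 1 of 1718 comparisons gained the call, under the other reading. Without intensities, signal over background could not be set against the calls.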

Other observations

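The tests on immediate early genes and on the size of the correlation between probes of a gene were chosen after the results were seen.

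Arc and Egr2, immediate early genes that cells switch on within minutes of a stimulus, were among the probes that turned with the dye, and a list of such genes was drawn up after this was seen. Of its 26 measured members 4 passed. Fosl2 had a turning part of 6.02 ± 0.49, Arc 5.92 ± 0.32 and Egr2 5.70 ± 0.36, each negative on the 4 arrays with ethanol in Cy3 and positive on the 4 with ethanol in Cy5. Nr4a2 turned the other way, at -3.01 ± 0.56 (limma adjusted p = 0.0275). Jun, Btg2 and Homer1 read -0.02 ± 0.29, 0.01 ± 0.43 and 0.03 ± 0.26. A common response of immediate early genes was tested on the 24 members other than Arc and Egr2: 18 were positive, with a median of 0.29 and an unadjusted p of 0.229 by limma's cameraPR. That decides neither for nor against a common response, since the members still include Fosl2 and the list was chosen from its leading genes.

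Probes for the same gene repeated each other weakly, and more in the shared part. Over 551 genes with exactly 2 tested probes the correlation between the probes, across genes, was 0.193 in the shared part (95% bootstrap interval 0.114 to 0.267; Spearman 0.197) and 0.054 in the turning part (-0.021 to 0.125; Spearman 0.017). The probes had the same sign for 57.2% of genes in the shared part and 49.5% in the turning part. The hypothesis that RNA differences lie mainly in the turning part was argued against by the difference of 0.139 (interval 0.035 to 0.244). Centring within brightness classes left 97.0% of the shared correlation, but 68.3% of the tested probes lie in 1 class, so the limit set before decided nothing and a brightness trend stays open. These values are consistent with the first reading, in which the ratios were deposited as 1 condition over the other, but sequence shared by the probes of a gene could add to the correlation, and the reading stays unsettled.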
